A study of Solanum lycopersicum with 12 samples.

How the data were processed

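The samples were flower pedicel abscission zones of tomato (Solanum lycopersicum) carrying a transgene that, per the labels, drives an antisense copy of a KD gene from the promoter of an abscission polygalacturonase (TAPG). No untransformed line is among the samples. Tissue was taken when the flower was removed (0 h) and at 5 later times, 4 h apart, up to 20 h, with 2 arrays per time and 12 arrays in all. Per the labels, the zone was attached at 0, 4 and 8 h and partially separated at 12, 16 and 20 h, the plants were held at 20 °C with 12 h of light, and 500 ng of RNA was amplified from an oligo-dT/T7 primer and labelled with Cy3. That labelling keeps the strand, so that sense and antisense probes measure different RNAs. The labels do not say whether the replicates came from separate plants; if they did not, the p-values measure only the spread between these samples.

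Per the file headers, the deposited array files hold the background-subtracted processed signal, the mean signal and the background signal of each spot as fluorescence intensity, made with Agilent Feature Extraction 11.5.1.1 and protocol GE1_1105_Oct12; the submitters' notes name the program without a version. The deposited spot flags (well above background, saturated, outlier) are of another kind, 0 or 1 for each spot. The deposited series matrix holds log2 values; its 12 columns follow the log2 processed signal of the array they are named for, less a constant per array that puts the 75th percentile near 0, which was found from the values because the labels do not state it. The labels state no genome build, and the probes carry contig names without positions, so no coordinates are given.

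The array has 180880 spots, of which 176026 are not controls, and 96152 distinct probes, of which 79874 have 2 spots. Of these probes, 50779 are sense and 45373 antisense to the named contig or gene. They carry 41686 names, of which 40419 are contigs and 205 are Arabidopsis loci; 8762 names are described as Unannotated and 5636 as Unknown Protein. The descriptions of 5393 probes state cross-hybridization with other transcripts. The arrays lie on 3 slides of 4 arrays, with 0 and 4 h on slide 1, 8 and 12 h on slide 2, and 16 and 20 h on slide 3. The pairs 4 against 0 h, 12 against 8 h and 20 against 16 h therefore lie within a slide, and in every other comparison slide and time cannot be told apart. Time of day also runs with the time since removal. Correlations between the residuals of equally numbered replicates ran from -0.372 to 0.194, and the numbers were not used as pairs.

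Spots with an outlier flag were left out where the probe had another spot, spots of a probe were averaged on the log2 scale, and the log2 value of the 75th percentile of each array's non-control spots was subtracted; the result is called the normalized log2 signal. Each gene or contig name was represented by its brightest probe over all arrays, on either strand. Names were tested when that probe was well above background on both arrays of at least 1 time, which left 35878 names, 34874 of them contigs; these are called transcripts. For 5965 of them the brightest probe was antisense, and for 4554 the description states cross-hybridization. The number of arrays limits the precision.

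One linear model with a coefficient per time and 6 residual degrees of freedom was fitted to all arrays with limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8), with moderated variances. Each later time was compared with 0 h, each time with the one before it, and the mean of 12, 16 and 20 h with the mean of 0, 4 and 8 h; a moderated F test covered the contrasts against 0 h. A transcript was called changed at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. The F test used the adjusted p alone. Errors of log2 fold changes are limma's standard errors (SE). The model was tested on simulated data with independent normal noise and, for each transcript, the model's pooled spread at every time. At 4 h it recovered 65.7% of changes of 1.5 log2 units, 82.1% of 2 and 95.5% of 3, and it called 10 of 35678 unchanged transcripts. A spread that differs between times was not simulated. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 read the files, and matplotlib 3.10.9 drew the plots.

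Where a probe was not well above background on any array of a time, its fold change is given as a bound: the other time's mean was compared with the lowest signal that counted as well above background on each array, and written as at least so many fold. Where it was above background on only some arrays of a time, that number is given and the size of the change is uncertain. The rule that chose the genes to name ordered transcripts by fitted log2 fold change, which for such probes rests on background signal, so the order is no ranking by size.

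The comparisons, the gene lists, the naming rule and the alternatives other than those listed as added were fixed before the data were examined. The rule named, for each time against 0 h and for partially separated against attached zones, up to 10 rises and 10 falls with the largest log2 fold change among called transcripts with a descriptive product name, when every later array lay beyond every reference array, 1 per identical description; for each successive step it named 4 and 4. In each list it named up to 4 called members with the largest change and up to 2 uncalled members with the highest signal. Single genes were matched by symbol, locus or accession and named whatever their values. The text gives a selection of the names the rule took. KD1, MBP21, ERF52, Nr, ETR4, ACO1, ACS2, ACS6, IAA3 and IAA9 matched no probe by these means and are not reported.

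The 37 gene lists were matched by words in the product descriptions. They cover wall enzymes (pectin-degrading enzymes, endoglucanases, expansins, xyloglucan endotransglucosylase/hydrolases), auxin (Aux/IAA proteins, auxin response factors, SAUR proteins, GH3 proteins, auxin transporters), ethylene (synthesis enzymes, receptors and signalling, response factors), other hormones (jasmonate synthesis and JAZ proteins, gibberellin metabolism, cytokinin metabolism and response, abscisic acid synthesis and response) and regulators (homeobox KNOX and BELL proteins, MADS-box proteins, meristem and boundary genes, WRKY factors, NAC factors). The others are pathogenesis-related proteins, chitinases and 1,3-glucanases; peroxidases; glutathione transferases; lignin and phenylpropanoid enzymes; cutin, suberin and wax enzymes; photosynthesis proteins; circadian clock genes; ribosomal proteins; cell cycle and histone genes; heat shock proteins; dehydration and late embryogenesis proteins; senescence and proteases; reference genes; and markers of pollen and anther, vascular and dividing-cell tissue. Word matching took in some members by chance in 19 lists, among them many in the pathogenesis-related list and some in the Aux/IAA list. Counts of list members include these unless stated otherwise, so such a count is not of the named proteins alone. Several names can also stand for the same gene, as Cel1 and U13054 do for CEL1, so members are not all separate genes. How many repeat a gene was not determined. Sets were tested against all other transcripts with limma's camera at a preset correlation of 0.01, over 185 tests of 37 lists at 5 times. Each list had at least 5 members, and p-values were adjusted over all 185. Members that repeat a gene may exceed that correlation, and the p-values may then be too small.

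The alternatives were quantile normalization, the array median in place of the 75th percentile, normexp background correction with an offset of 50, the deposited log2 values, no filter on dim probes, probes above background on all arrays, the mean of a name's detected probes, every probe by itself, array weights, a trended and robust prior, the replicate number as a block, slide as a block, adjusted p alone, only the arrays compared, 4 and 8 h alone as the reference, each array left out in turn, and for the lists an estimated correlation in camera and limma's fry. Sense-strand probes alone, lists without members matched by chance and lists without replicate 1 at 12 h were added after the data were seen. A count was taken as moved when it changed by more than 1.5 times. Other groupings of the arrays were drawn with a fixed seed.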

Results

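RNA of tomato flower pedicel abscission zones was measured on 12 single-colour arrays, with 2 arrays at each of 6 times from 0 to 20 h after flower removal. All samples carried the TAPG::antisense KD transgene. The 75th percentile of the signal ran from 140.7 units on replicate 1 at 12 h to 261.5 units on replicate 1 at 0 h, and 52% to 60.2% of the probes were well above background. No spot was saturated. Replicates correlated across probes with r between 0.9826 at 12 h and 0.9931 at 0 h, where probes are not independent replicates. The first principal component held 62.2% of the variance and the second 15%. Every log2 fold change below comes from limma with its SE and n = 2 arrays per time, and signals are normalized log2 signals with their SD. Of the transcripts called in a comparison of a pair of times, each had both arrays of the later time beyond both arrays of the earlier time, except 1 at 20 h (11729 of 11730). Chance gives that order in 33.3% of transcripts not selected by the test, and called ones were selected on this difference.

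The comparisons with 0 h ask which transcripts changed after the flower was removed. At 4 h, 3576 of 35878 transcripts passed the test, of which 2225 rose and 1351 fell. The count was 7910 at 8 h (4253 rose, 3657 fell), 12115 at 12 h (5866 and 6249), 13011 at 16 h (6277 and 6734) and 11730 at 20 h (5740 and 5990). The F test over all times gave 22816 at an adjusted p under 0.05, with no minimum fold change, unlike the counts above. With the array median as the scale, the median log2 fold change of all transcripts moved to -0.13 at 4 h, -0.24 at 8 h, -0.27 at 12 h, -0.40 at 16 h and -0.23 at 20 h, from -0.02 at 16 h in the fit reported. The share of called transcripts that rose then changed from 62.2% to 52.8% at 4 h, from 53.8% to 40.5% at 8 h, from 48.4% to 36.5% at 12 h, from 48.2% to 30.5% at 16 h and from 48.9% to 36.7% at 20 h. The count at 4 h rested in part on single arrays: it was 1756 without replicate 1 and 2331 without replicate 2 at 0 h, and 2121 without replicate 2 at 4 h.

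**Figure D1:**
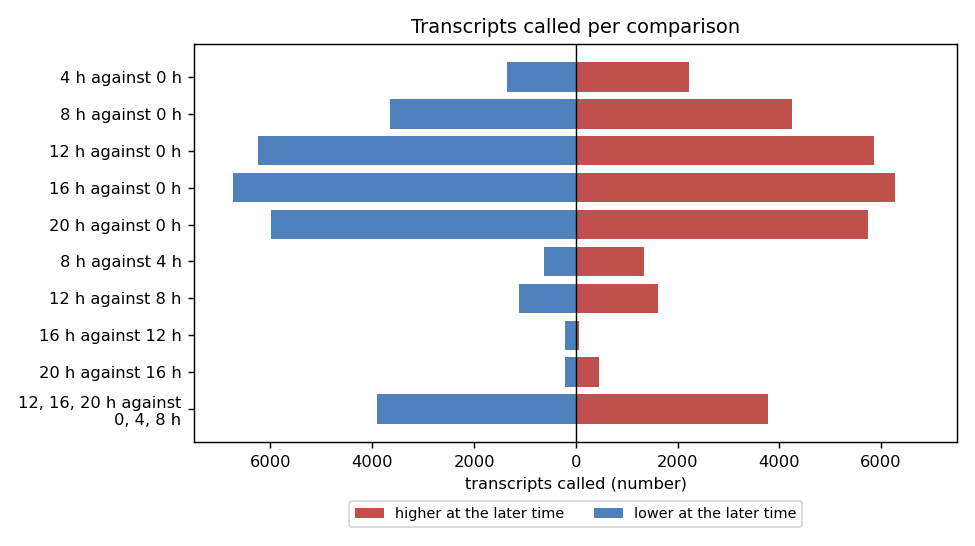
Number of transcripts called higher (bars to the right) and lower (bars to the left) in each comparison, with the number of transcripts on the x axis. Calls against 0 h grew from 3576 at 4 h to 13011 at 16 h, and the step from 12 to 16 h called 278.

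The abscission polygalacturonases TAPG1 and TAPG2, which break down pectin between cells, came up from below background. TAPG1 (U23053) was not above background at 0 h and stood at -0.38 ± 1.2 at 4 h, 4.50 ± 1.69 at 8 h, 8.21 ± 0.55 at 12 h and 9.52 ± 0.06 at 20 h. It was at least 21.4-fold higher than at 0 h by 4 h (adjusted p = 0.0019) and at least 20400-fold higher by 20 h (adjusted p = 4.41e-06). TAPG2 (U70480) was at least 23.5-fold higher at 4 h (adjusted p = 0.00364) and at least 15500-fold higher at 20 h (adjusted p = 1.04e-05). TAPG4 (U70481) was already at 4.85 ± 0.53 at 0 h and rose 8.53-fold by 4 h (log2 3.09 ± 0.31, adjusted p = 8.43e-04) and 19.7-fold by 12 h. TAPG3 (AF000999) was below background on all 12 arrays and was not tested.

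The cellulases, which hydrolyse glucans of the cell wall, followed later. CEL5 (AF077339) was 42.4-fold higher at 12 h (log2 5.41 ± 0.45, adjusted p = 6.08e-05) and 240-fold higher at 20 h (log2 7.90 ± 0.45, adjusted p = 9.59e-06). CEL1 (Cel1) stood at log2 0.36 ± 0.33 at 4 h, which did not pass the test, and rose 12.7-fold by 12 h (log2 3.67 ± 0.33, adjusted p = 8.32e-05) and 17.6-fold by 20 h. CEL2 (U13055) did not pass the test at 4 h (log2 -0.45) or 8 h (log2 -0.28) and rose 6.92-fold by 20 h (log2 2.79, adjusted p = 1.07e-04). The rises of CEL5 (log2 1.65) and CEL1 (log2 1.27) at 8 h were called but fragile. CEL5 lost the call when any 1 of the 4 arrays was left out (log2 1.41 and 1.89 without replicate 1 and 2 at 0 h, 1.81 and 1.49 without those at 8 h). CEL1 lost it without replicate 2 at 0 h (log2 1.00) or replicate 1 at 8 h (log2 1.05), and its second probe set, U13054, was not called (log2 0.98). At 12 h CEL2 stood at log2 1.17, and without replicate 2 at 0 h it was 1.02 and no longer called. The probes of TAPG1, TAPG2, TAPG4 and CEL5 state cross-hybridization, as do those of the polygalacturonases contig12772, contig19603 and contig30774, so their separate courses are uncertain. Further transcripts named below whose probes state it are contig5685, contig10337, contig27759, contig2773, contig600, contig8154, contig29973, contig7996 and contig30535. It is not marked beside every other transcript.

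**Figure D2:**
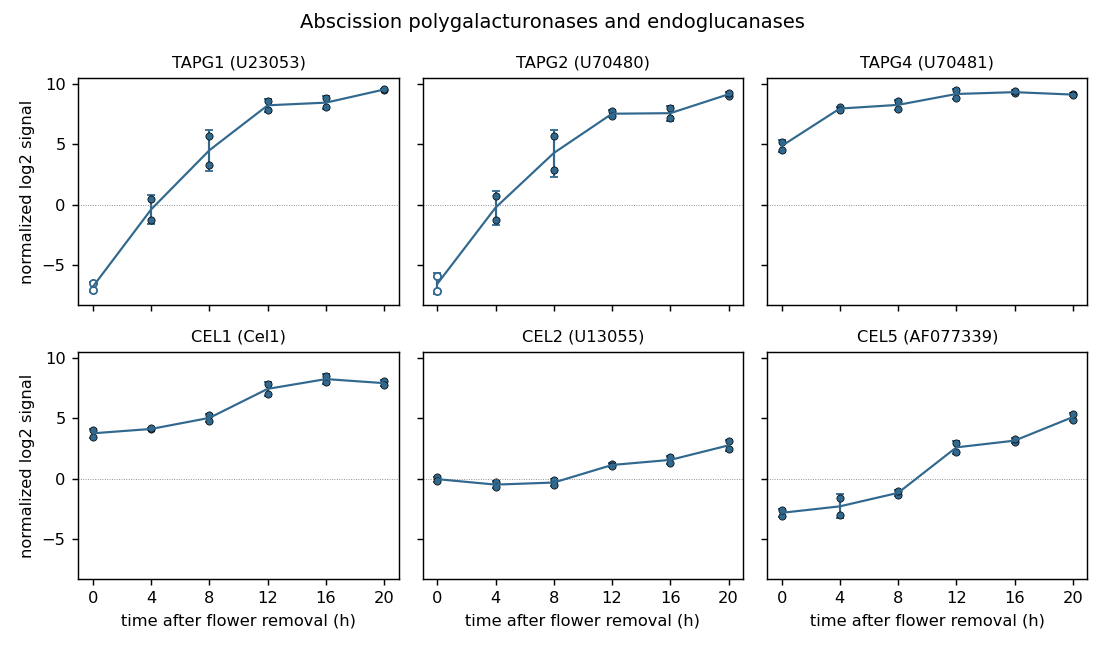
Normalized log2 signal (y axis) against hours after flower removal (x axis) for 3 polygalacturonases and 3 cellulases; points are arrays, open points were not well above background, and lines join means ± SD of 2 arrays. TAPG1 reached 9.52 ± 0.06 at 20 h, from a level below background at 0 h.

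By 4 h several transcripts of auxin response had fallen. The SAUR transcripts contig5685 and contig28328, members of a family of small proteins induced by auxin, were at least 20.1-fold and at least 31.8-fold lower (adjusted p = 1.02e-04 for contig5685). The auxin-responsive contig27759 fell by 5.31 ± 0.43 log2 units (adjusted p = 4.3e-04), and auxin response factor 9 (contig23639) fell by 4.95 ± 0.49 (adjusted p = 7.69e-04), the latter above background on 1 of 2 arrays at 4 h. The probes of contig5685 and contig27759 state cross-hybridization. An amino acid transporter (contig7332) and a spermidine synthase (contig19737) were at least 26.8-fold and at least 11.8-fold lower. Among the rises were a cytochrome P450 (contig19753), at least 195-fold higher (adjusted p = 3.53e-04), and a bHLH protein (contig9425), at least 57.3-fold higher (adjusted p = 6.08e-04). Polygalacturonase 1 (contig19603) was at least 25.9-fold higher. Proteinase inhibitor II (contig21442), which blocks digestive proteases of herbivores, rose by log2 5.48 ± 0.32 (adjusted p = 2.07e-04).

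Auxin response lists were down at 4 h. Where a count adjusted over the list alone is not given beside a list, it was the same as the count over all transcripts. Of 27 Aux/IAA proteins, the repressors of auxin-responsive genes, 17 fell and 0 rose by limma (20 fell adjusted over the list alone; 23 lower and 1 higher at an unadjusted p under 0.05), with a median log2 fold change of -2.46; IAA11 fell by 4.56 ± 0.41 (adjusted p = 5.35e-04), above background on 1 of 2 arrays at 4 h, and contig30824 did not pass the test. Word matching put some auxin response factors into that list, and 14 of the 20 members left without them fell. Of 74 SAUR proteins 38 fell and 4 rose (41 and 6 adjusted over the list alone), and contig19520 fell by 5.40 ± 0.51. Of 32 auxin response factors 5 fell and 3 rose (6 and 3 adjusted over the list alone), and contig19789 (factor 24) rose by log2 1.88 ± 0.17 (adjusted p = 6.08e-04). Camera called all of these lists down, with adjusted p = 4.03e-14, 9.38e-13 and 1.42e-04, and for each the adjusted p was 0.401 with an estimated correlation. Of 19 auxin transporters 5 fell and 1 rose, with no call for the list, and the carrier contig2587 fell by 2.84 ± 0.27. Of 26 GH3 proteins, which conjugate auxin to amino acids, 1 fell and 0 rose by limma (0 and 0 adjusted over the list alone; 6 lower and 2 higher at an unadjusted p under 0.05).

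Jasmonate and defence lists moved the other way at 4 h. Of 58 jasmonate synthesis and JAZ transcripts 23 rose and 2 fell (25 and 2 adjusted over the list alone; camera adjusted p = 6.74e-05); the repressor TIFY 5A (contig11382) rose by log2 3.25 ± 0.50 and a lipoxygenase (contig13892) by 2.68 ± 0.45, while JAZ2 (contig28502) at log2 0.96 was not called. Of 70 NAC factors 16 rose and 4 fell (17 and 5 adjusted over the list alone; adjusted p = 0.00619). Of 280 pathogenesis-related proteins, chitinases and 1,3-glucanases 61 rose and 14 fell (69 and 18; adjusted p = 0.0087; 47 and 4 of the 147 members left without chance matches of words), and of 71 WRKY factors 9 rose and 3 fell (adjusted p = 0.0276), with contig27233 rising by log2 2.78 ± 0.36. With an estimated correlation each of these 4 lists had an adjusted p of 0.401. Of 139 lignin and phenylpropanoid enzymes 20 rose and 0 fell by limma (41 higher and 10 lower at an unadjusted p under 0.05; list adjusted p = 0.0135; 0.542 with an estimated correlation), and laccase 1a (contig21988) rose by log2 3.74 ± 0.42. Of 68 glutathione transferases 6 rose and 1 fell (adjusted p = 0.0261; 0.627 with an estimated correlation), and contig21761 rose by log2 2.29 ± 0.32. Of 21 vascular markers 2 rose and 0 fell by limma (5 higher and 0 lower at an unadjusted p under 0.05; list adjusted p = 0.0366; 0.639 with an estimated correlation), and the phloem protein contig7198 rose by log2 1.53 ± 0.17.

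Photosynthesis and ribosomal transcripts were the other lists called at 4 h. Of 167 photosynthesis proteins 21 fell and 1 rose (23 and 1 adjusted over the list alone), and the chlorophyll a-b binding protein contig30158 fell by 1.62 ± 0.18 (adjusted p = 0.00134). The list test gave an adjusted p of 2.99e-12, and 0.639 with an estimated correlation. Of 431 ribosomal proteins 2 rose and 1 fell (0 and 0 by limma adjusted over the list alone, 11 and 40 at an unadjusted p under 0.05), 1 rose and 2 fell with the array median as the scale, and the test called the list down with a median log2 fold change of -0.07 (adjusted p = 0.0478; 0.913 with an estimated correlation; 0.0692 without replicate 1 at 12 h).

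At 8 h, with the zone still attached, the transcript of an ACC synthase (contig12431), which makes the precursor of ethylene, was at least 137-fold higher than at 0 h (adjusted p = 7.77e-05). Polygalacturonase 1 (contig12772) was at least 644-fold and the cytochrome P450 contig19753 at least 434-fold higher. A CONSTANS-like protein (contig8154), of a family that times flowering, rose by log2 8.23 ± 0.44 (adjusted p = 1.82e-05; 1 of 2 arrays above background at 0 h). The falls included the SAUR transcripts contig28328, at least 44.6-fold lower, and contig10337, which fell by 6.50 ± 0.50 (adjusted p = 7.35e-05; 1 of 2 arrays above background at 8 h). A gibberellin 2-dioxygenase (contig18619), which inactivates gibberellins, fell by 6.47 ± 0.67 (adjusted p = 2.68e-04), and a cytochrome P450 (contig17910) fell by 6.42 ± 0.54.

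Of 25 circadian clock genes 11 fell and 1 rose at 8 h (adjusted p = 3.05e-04; 0.401 with an estimated correlation): the GIGANTEA fragment contig13217 fell by 5.41 ± 0.19, pseudo-response regulator 5 (contig5525) fell by 3.97 ± 0.23, and the LHY-like contig11716, a morning factor of the clock, rose by log2 6.30 ± 0.15 (adjusted p = 6e-07). Of 139 lignin and phenylpropanoid enzymes 54 rose and 9 fell (56 and 9 adjusted over the list alone; adjusted p = 1.09e-05). Of 58 jasmonate transcripts 28 rose and 3 fell (29 and 4; adjusted p = 5.42e-04), the lipoxygenase contig14746 being at least 30.2-fold higher. Of 280 pathogenesis-related transcripts 90 rose and 32 fell (93 and 34; adjusted p = 0.00637), of 70 NAC factors 19 and 8 (20 and 8; adjusted p = 0.00758), and of 71 WRKY factors 17 and 3 (19 and 3; adjusted p = 0.0418, or 0.0554 without replicate 1 at 12 h; the median WRKY change, log2 0.18, was -0.02 with the array median as the scale). Down were Aux/IAA (21 of 27, adjusted p = 1.13e-09), SAUR (38 of 74, adjusted p = 1.07e-04) and auxin response factors (11 of 32, adjusted p = 6.45e-04). In the same order, 1, 15 and 4 members were higher at an unadjusted p under 0.05 by limma. All of these lists had an adjusted p of 0.401 with an estimated correlation. Photosynthesis (18 of 167 fell, 6 rose; adjusted p = 2.0e-04), cell cycle and histone genes (12 of 131 fell, 8 rose; adjusted p = 0.00543) and ribosomal proteins (35 of 431 fell, 10 rose; adjusted p = 4.84e-06) were also called down; with normexp the cell cycle split was 7 and 7. With an estimated correlation these gave 0.838, 0.639 and 0.781.

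At 12 h, the first time with partial separation, polygalacturonase transcripts were among those named. Polygalacturonase 1 (contig12772) was at least 8020-fold higher than at 0 h (adjusted p = 5.69e-06) and polygalacturonase A (contig14567) at least 489-fold. The cytochrome P450 contig19753 was at least 2370-fold and an FAD-binding protein (contig2773) at least 1340-fold higher. The proteinase inhibitor CEVI57 (contig25506) rose by log2 10.06 ± 0.65 (adjusted p = 1.95e-05). An auxin efflux carrier (contig13300), which exports auxin from cells, fell by 7.63 ± 0.95 (adjusted p = 3.62e-04), a pectinesterase (contig5679) fell by 7.49 ± 0.47 (adjusted p = 1.78e-05) and a GDSL esterase (contig24456) fell by 7.16 ± 0.56; each was above background on 1 of 2 arrays at 12 h. An F-box protein with kelch repeats (contig6853) fell by 6.21 ± 0.19 (adjusted p = 1.06e-06), and IAA11 was at least 22.6-fold lower.

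Ethylene synthesis, peroxidase and xyloglucan lists joined the defence lists at 12 h. Of 86 ethylene synthesis enzymes 34 rose and 5 fell (adjusted p = 0.00928; 0.551 with an estimated correlation), the ACC synthase contig11180 rose by log2 6.95 ± 0.64 and the ACC oxidase contig14862 by 6.64 ± 0.51, while the oxidase contig9908 at log2 0.19 was not called. Of 35 xyloglucan endotransglucosylase/hydrolases, which cut and rejoin wall xyloglucan, 15 rose and 7 fell (adjusted p = 0.0377; 0.639 with an estimated correlation), and contig18543 rose by log2 7.40 ± 0.93. Of 85 peroxidases 39 rose and 14 fell (40 and 15 adjusted over the list alone; adjusted p = 0.00619), with contig16273 rising by log2 8.74 ± 1.07, and of 23 dehydration proteins 12 rose and 2 fell (adjusted p = 0.00449); both gave 0.401 with an estimated correlation. Of 68 glutathione transferases 24 rose and 5 fell (adjusted p = 0.00758; 0.532), and contig3019 rose by log2 4.24 ± 0.30. Lignin enzymes (51 rose, 18 fell; adjusted p = 0.00133), pathogenesis-related proteins (118 and 46; 0.00268), WRKY factors (27 and 9; 0.00622) and NAC factors (25 and 8; 0.0276) were up, with 0.401 for each under an estimated correlation except 0.427 for NAC factors.

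Lists that fell at 12 h included those of auxin response. Of 27 Aux/IAA proteins 23 fell and 1 rose (adjusted p = 8.97e-08; 0.401 with an estimated correlation), and of 32 auxin response factors 18 fell and 2 rose (adjusted p = 2.6e-04; 0.401), where factor 4 (contig16602) fell by 4.33. Of 74 SAUR proteins 39 fell and 16 rose (adjusted p = 0.0205; 0.639), with contig1672 rising by log2 5.62 ± 0.21 (adjusted p = 2.57e-06). Of 131 cell cycle and histone genes 34 fell and 7 rose (35 and 7 adjusted over the list alone; adjusted p = 0.00159; 0.611), and the D5 cyclin contig1989 rose by log2 3.17 ± 0.21. Of 431 ribosomal proteins 51 fell and 12 rose (adjusted p = 5.97e-04; 0.845), and of 25 clock genes 9 fell and 2 rose (adjusted p = 0.00566; 0.406). Among the clock genes the LHY-like contig11716 rose by log2 7.13 ± 0.15 and the ELF4-like contig30655 fell by 4.82 ± 0.33.

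At 16 h the regulatory protein contig8645 was at least 581-fold higher than at 0 h (adjusted p = 3.35e-07), polygalacturonase A (contig14567) at least 829-fold and a MYB factor (contig24707) at least 938-fold. A cathepsin B (contig26249), a cysteine protease, rose by log2 12.37 ± 1.31. At 0 h it stood at -3.91 ± 3.63 with 1 of 2 arrays above background, so the size is uncertain. The auxin efflux carrier contig13300 was at least 202-fold lower (adjusted p = 1.01e-04), and a ZF-HD homeobox protein (contig25944) at least 152-fold lower. A germin (contig13037) fell by 7.52 ± 0.70 (adjusted p = 7.86e-05) and the cytochrome P450 contig17910 fell by 7.37 ± 0.54 (adjusted p = 2.55e-05).

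The lists called at 16 h were up for ethylene synthesis (35 rose, 6 fell; adjusted p = 0.012, or 0.565 with an estimated correlation), dehydration proteins (11 and 3; 0.0261, or 0.406), lignin enzymes (49 and 22; 0.035, or 0.627), pathogenesis-related proteins (115 and 56, or 116 and 57 adjusted over the list alone; 0.0205), peroxidases (42 and 15; 0.00558), WRKY factors (29 and 10; 0.00758) and NAC factors (28 and 9; 0.00758); the last 4 gave 0.401. The lignin call was lost without replicate 1 at 12 h (0.0594), and the median lignin change, log2 0.38, was 0.00 with the array median as the scale. Down were Aux/IAA (23 fell, 1 rose; adjusted p = 4.64e-08), auxin response factors (17 and 2; 2.0e-04), SAUR (39 and 14; 0.00622), ribosomal proteins (108 and 8; 2.79e-11), cell cycle and histone genes (49 and 8; 6.45e-04) and clock genes (9 and 2; 0.0146). With an estimated correlation the adjusted p for these was 0.401, 0.401, 0.589, 0.639, 0.565 and 0.506. SAUR contig1672 rose by log2 6.26 ± 0.21 against the run of its family, and the benzoyltransferase contig22817 by 6.38 ± 0.45.

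At 20 h a wall enzyme and a protease inhibitor were among the rises. Polygalacturonase 1 (contig12772) was at least 21400-fold higher than at 0 h, the regulatory protein contig8645 at least 866-fold and an acyltransferase (contig600) at least 649-fold. A Kunitz-type protease inhibitor (contig182) rose by log2 11.11 ± 1.01 (adjusted p = 7.18e-05). Among the falls, the cytochrome P450 contig17910 fell by 8.40 ± 0.54 (adjusted p = 1.48e-05) and the germin contig13037 fell by 7.87 ± 0.70 (adjusted p = 6.54e-05). The pectinesterase contig5679 was at least 360-fold lower, the GDSL esterase contig24456 at least 123-fold, and hydroxycinnamoyl quinate transferase (contig7996), a phenylpropanoid enzyme, at least 76.5-fold.

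At 20 h pectin-degrading enzymes and endoglucanases were called as lists, and expansins and xyloglucan endotransglucosylase/hydrolases were not. Of 127 pectin-degrading enzymes 47 rose and 17 fell (adjusted p = 0.0176; 0.401 with an estimated correlation), contig30774 being at least 15800-fold higher, while the pectinesterase contig22635 (log2 -0.47) was not called. Of 43 endoglucanases 20 rose and 6 fell (adjusted p = 0.0148; 0.532), and contig31060 rose by log2 7.79 ± 0.41 (adjusted p = 6.06e-06). Of 85 peroxidases 45 rose and 10 fell (47 and 10 adjusted over the list alone; adjusted p = 0.00188; 0.401), with contig11844 rising by log2 8.08 ± 0.64, and of 86 ethylene synthesis enzymes 34 rose and 8 fell (adjusted p = 0.00312; 0.445), with the ACC oxidase contig22055 rising by log2 5.77 ± 0.49. WRKY factors (31 rose, 6 fell; adjusted p = 8.28e-05), NAC factors (24 and 7; 0.0147) and dehydration proteins (10 and 2; 0.0147) each gave 0.401, pathogenesis-related proteins (111 and 57, or 112 and 59 adjusted over the list alone; 0.0258) gave 0.406 and lignin enzymes (49 and 25, or 51 and 25; 0.028) gave 0.614 with an estimated correlation. WRKY factor 5 (contig13565) rose by log2 5.48 ± 0.17 (adjusted p = 1.14e-06), and CEVI57 (contig25506) by 10.72 ± 0.65. Against the run of the ethylene synthesis list, the ACC oxidase-like contig25238 was at least 97.8-fold lower (adjusted p = 8.27e-06).

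Down at 20 h were 23 of 27 Aux/IAA proteins (adjusted p = 8.68e-09; 0.401 with an estimated correlation), 14 of 32 auxin response factors (5.68e-04; 0.401), 35 of 74 SAUR proteins (0.0186; 0.639), 11 of 19 auxin transporters (0.028; 0.401), 106 of 431 ribosomal proteins (4.03e-14; 0.627) and 27 of 131 cell cycle and histone genes (0.0125; 0.643). At an unadjusted p under 0.05 by limma, 1, 4, 15, 3, 27 and 20 members of these lists, in that order, were higher. The auxin carrier contig2587 fell by 3.92 (1 of 2 arrays above background at 20 h), the ribosomal protein L37a (contig26209) fell by 2.63 ± 0.31, and a cyclin-dependent kinase (contig13779) was at least 27.7-fold lower. Factor 9 of the auxin response factors (contig335) rose by log2 2.20 ± 0.20. Over the 5 times, camera called 67 of 185 tests and 0 with an estimated correlation, where 16 had an unadjusted p under 0.05 and the lowest adjusted p was 0.401; limma's fry, which asks whether a list's members move one way on balance, called 102.

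**Figure D3:**
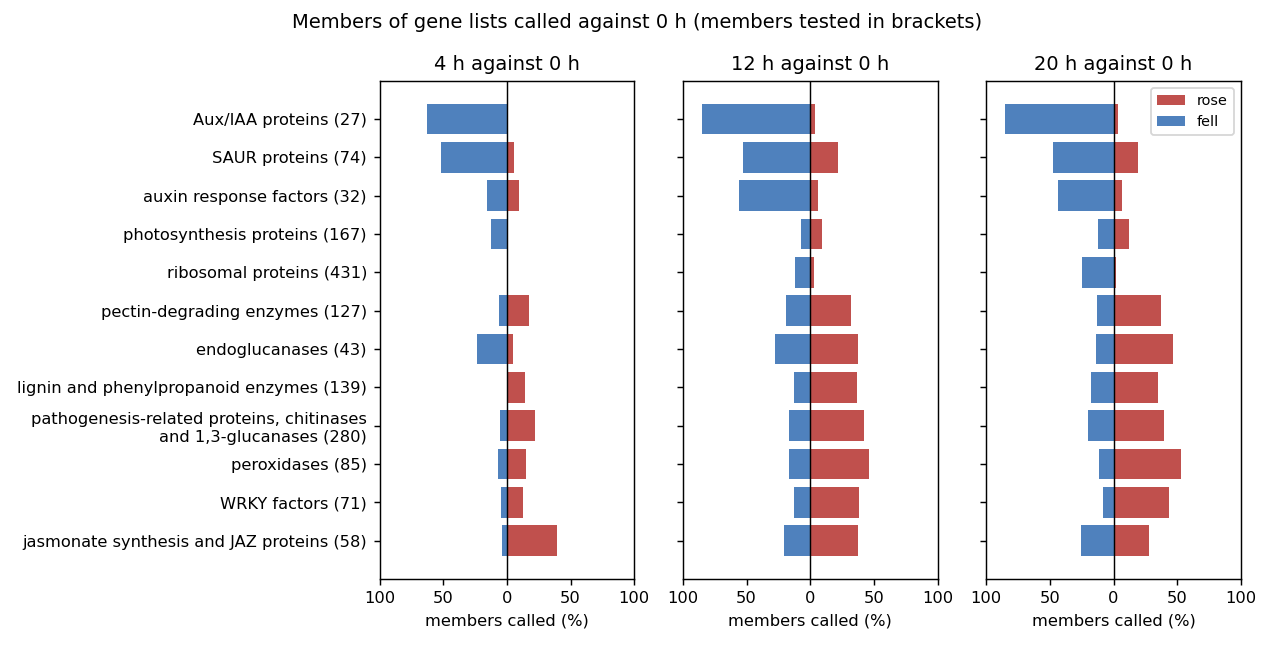
Percentage of the tested members of 12 lists (x axis) that rose or fell at 4, 12 and 20 h against 0 h, with bars to the right for rises and to the left for falls. Aux/IAA proteins fell at each of these times (17, 23 and 23 of 27 members). Members matched by chance of words are included.

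Steps between successive times ask when the changes came. From 4 to 8 h 1964 transcripts passed the test (1337 rose, 627 fell). A GCN5-related N-acetyltransferase (contig19712) was at least 109-fold and a CONSTANS-like protein (contig29973) at least 119-fold higher at 8 h, and the GIGANTEA fragment contig13217, a clock gene, fell by 5.16 ± 0.19 (adjusted p = 7.67e-06). The pentatricopeptide protein contig3098 fell by 4.83 ± 0.46 (adjusted p = 8.25e-04). The count was 830 without replicate 2 at 4 h, 1023 without replicate 2 and 1282 without replicate 1 at 8 h, and 1478 without replicate 1 at 4 h (within 1.5 times).

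From 8 to 12 h, across the onset of partial separation, 2718 transcripts passed (1611 rose, 1107 fell). The acyltransferase contig600 was at least 115-fold higher (adjusted p = 6.14e-04), a DC1 domain protein (contig4770) at least 15.5-fold and a zinc finger protein (contig13411) at least 41.2-fold. A zinc transporter (contig1342) fell by 4.34 ± 0.66 (adjusted p = 0.00781; 1 of 2 arrays above background at 12 h) and bHLH79 (contig20715) fell by 4.07 ± 0.57 (adjusted p = 0.00623). The count was 766 without replicate 1 at 12 h and 5116 without replicate 2 at 12 h, and 1418 and 1046 without replicates 1 and 2 at 8 h. Replicate 1 at 12 h was the dimmest array.

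From 12 to 16 h 278 transcripts passed (60 rose, 218 fell). A disease resistance protein (contig20461) fell by 4.45 ± 0.48 (adjusted p = 0.0104) and the ELF4-like contig30655, a clock gene, rose by log2 2.49 ± 0.33 (adjusted p = 0.0202), a call lost without replicate 2 at 12 h (2.11). The other transcripts the rule named here, such as the nodulin-related contig19166 (log2 2.59 ± 0.39, or 2.10 without replicate 2 at 12 h), also lost their calls when single arrays were left out. The count was 45 without replicate 2 at 16 h, 184 without replicate 2 at 12 h, and 281 without replicate 1 at 12 h. With the 4 arrays compared alone limma called 0, with 3188 at an unadjusted p under 0.05.

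From 16 to 20 h 677 transcripts passed (465 rose, 212 fell). A nitrate transporter (contig13074) was at least 12-fold higher (adjusted p = 0.0021), a light-regulated protein (contig251) rose by log2 5.33 ± 0.53 (adjusted p = 0.0038) and a cytochrome P450 (contig30535) by 5.16 ± 0.49 (adjusted p = 0.00277). A ubiquitin-conjugating enzyme (contig21726) fell by 5.29 ± 0.34 (adjusted p = 8.64e-04) and a peroxisomal membrane protein (contig14317) fell by 4.09 ± 0.39 (adjusted p = 0.00309). The share that rose was 68.7%, and 80.7% with the array median as the scale, which moved the median of all transcripts to log2 0.15. The count was 123 without replicate 2 and 439 without replicate 1 at 20 h, and 404 without replicate 1 at 16 h. With the 4 arrays compared alone limma called 0, with 4999 at an unadjusted p under 0.05.

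Partially separated zones (6 arrays at 12, 16 and 20 h) were set against attached zones (6 arrays at 0, 4 and 8 h), and 7685 transcripts passed, 3770 higher and 3915 lower. The SEs and p-values here rest on the spread between replicates of a time. They do not measure the spread between the times of a state, and state cannot be told apart from time. CEL5, for example, had an SD of 1.21 over the separated and 0.89 over the attached arrays, against an SE of 0.26. Polygalacturonase 1 (contig12772) was higher by log2 9.59 ± 0.40 (adjusted p = 1.56e-06; 4 of 6 attached arrays above background, so the size is uncertain), CEL5 (AF077339) by 5.70 ± 0.26, CEL1 (Cel1) by 3.55 ± 0.19 and CEL2 (U13055) by 2.09 ± 0.16. The regulatory protein contig8645 was higher by log2 8.15 ± 0.16 (adjusted p = 1.26e-07; 4 of 6, likewise uncertain in size) and a cytochrome P450 (contig21490) by 7.25 ± 0.46. The pectinesterase contig5679 fell by 6.21 ± 0.27 (adjusted p = 1.95e-06) and the auxin efflux carrier contig13300 fell by 5.51 ± 0.55. Each was above background on 1 of 6 separated arrays, so both sizes are uncertain. A pistil extensin (contig29619), a wall glycoprotein, fell by 4.84 ± 0.24 (adjusted p = 3.13e-06). Of 127 pectin-degrading enzymes 37 were higher and 12 lower, of 43 endoglucanases 20 and 4, of 85 peroxidases 42 and 10, of 27 Aux/IAA proteins 1 and 17, and of 58 jasmonate transcripts 10 and 17. In 4394 of the called transcripts (57.2%) all 6 separated arrays lay beyond all 6 attached arrays. Chance gives 0.216% among transcripts not selected by the test, which is no measure for called ones. The share that was higher, 49.1%, was 37.2% with the array median as the scale, which put the median of all transcripts at log2 -0.19; against 4 and 8 h alone 5831 transcripts passed.

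The transgene is antisense to a KD gene, a knotted-like homeobox gene, and no probe could be matched to KD1 by symbol, locus or accession. Among contigs described as knotted-like homeobox proteins, contig17683 showed opposite courses on its strands, and whether it is the targeted gene was not established. Its antisense probe rose from -0.99 ± 0.96 at 0 h to 4.13 ± 1.83 at 4 h, 6.20 ± 0.31 at 12 h and 5.90 ± 0.34 at 20 h (log2 fold change 7.19 ± 0.76 at 12 h, adjusted p = 1.81e-04, n = 2). The sense probe stood at -0.57 ± 0.38 at 0 h and -3.09 ± 0.79 at 4 h, which did not pass the test (adjusted p = 0.0669), and was below background on every array from 12 h on, at least 12.3-fold lower at 12 h and at least 12.6-fold lower at 20 h.

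**Figure D4:**
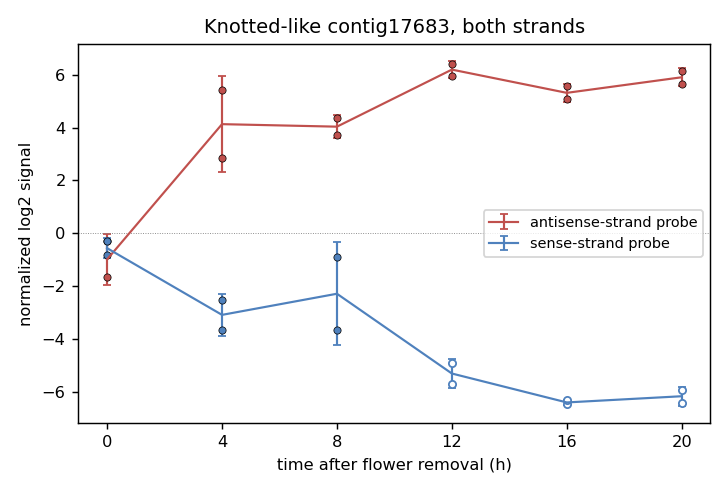
Normalized log2 signal (y axis) of the sense and the antisense probe of contig17683 against hours after flower removal (x axis); points are arrays, open points were not well above background, and lines join means ± SD of 2 arrays. The antisense probe stood at -0.99 ± 0.96 at 0 h and 6.20 ± 0.31 at 12 h, and the sense probe at -0.57 ± 0.38 and -5.31 ± 0.55.

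Of 26 homeobox KNOX and BELL transcripts, regulators of meristem identity, 1 rose and 6 fell at 4 h (1 and 8 adjusted over the list alone), 5 rose and 7 fell at 12 h, and 5 rose and 7 fell at 20 h, with contig17683 counted by its antisense probe; the list was never called. At 12 h the LeKNOTTED_C1_(LEAF000141) transcript fell by 3.01 ± 0.39, the homeobox protein H1 (contig13844) fell by 2.75 ± 0.37 (adjusted p = 4.88e-04) and BEL1-like 9 (contig193) fell by 3.49 ± 0.29 (adjusted p = 6.01e-05). BEL1-like 1 (contig19438) was not called at 4, 12 or 20 h (log2 0.40, -0.33 and -0.19). The probes of LeKNOTTED_C1_(LEAF000141) and contig13844 state cross-hybridization.

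Of the other genes named in advance, BLIND (LOC543703), a MYB factor of axillary meristems, rose 10.2-fold by 20 h (log2 3.36), and its second probe set (NM_001247714) by log2 3.16. LATERAL SUPPRESSOR (Ls), a GRAS factor of lateral meristems, did not pass the test at 4 h (log2 0.29) and was 4.07-fold lower by 20 h (log2 -2.02); its fall at 12 h (log2 -1.29 ± 0.31, adjusted p = 0.00748) was not called without replicate 1 at 12 h (-0.99). MACROCALYX (contig12485), a MADS-box gene of the pedicel, stood at log2 -1.51 at 16 h and -1.16 at 20 h, both called, and at -1.26 ± 0.25 at 12 h (-0.93 and not called without replicate 1 at 12 h). JOINTLESS (AAG09811), the MADS-box gene needed to form the zone, was not called at any time (log2 -0.58 at 4 h, adjusted p = 0.0586). At 8, 12, 16 and 20 h it stood at log2 -0.73, -0.52, -0.73 and -0.81 (adjusted p = 0.0134, 0.0357, 0.00813 and 0.00522) and missed the call on the size of the change alone. These values come from its brightest probe, which is antisense and states cross-hybridization. The sense probe of AAG09811, which states it too, was not called either (log2 -0.44, -0.75, -0.37, 0.15 and -0.40 from 4 to 20 h, adjusted p = 0.0302 at 8 h and above 0.05 otherwise).

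The remaining lists were not called at any time. Of 31 expansins, which loosen walls, 2 rose and 8 fell at 4 h (2 and 9 adjusted over the list alone), and 13 rose and 5 fell at 20 h, where contig4245 was at least 20.5-fold higher and contig27820 at least 20.5-fold lower; at 16 h the split of 11 and 8 was 9 and 10 with the array median. Of 138 ethylene response factors 30 rose and 36 fell at 12 h, contig13176 being at least 62.5-fold higher, and the split of 14 and 14 at 4 h (15 and 16 adjusted over the list alone) was 11 and 17 with the array median. Of 31 ethylene receptors and signalling transcripts 2 rose and 3 fell at 12 h, the receptor contig19923 among the latter (log2 -1.75 ± 0.41), and the split of 2 and 2 at 20 h was 2 and 5 with the array median. Of 71 MADS-box transcripts 11 rose and 6 fell at 12 h (7 and 10 with the array median), and contig13399 rose by log2 4.10 ± 0.31. Of 36 meristem and boundary genes 10 rose and 9 fell at 12 h (7 and 10 with the array median), and LOB domain protein 25 (contig25353) rose by log2 6.92 ± 0.37.

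Hormone lists without a call were also divided. Of 31 gibberellin metabolism transcripts 8 rose and 7 fell at 12 h (7 and 9 with the array median), a 20-oxidase (contig17199) rose by log2 5.31 ± 0.59 and, at 20 h, a 3-hydroxylase (contig9678) fell by 6.97 ± 0.91. Of 29 cytokinin transcripts 8 rose and 8 fell at 12 h (8 and 9 adjusted over the list alone; 7 and 10 with the array median), and the cytokinin oxidase contig9453 rose by log2 5.27 ± 0.42. Of 21 abscisic acid transcripts 4 rose and 2 fell at 20 h (3 and 3 with the array median), and the receptor PYR1 (contig27662) rose by log2 1.81 ± 0.14 (adjusted p = 3.26e-05). Of 26 GH3 proteins 6 rose and 6 fell at 12 h, and 8 and 8 at 16 h (7 and 8 with the array median). Medians and means of lists differed in sign for gibberellin metabolism at 4 h (0.24 and -0.07), cytokinin at 8 h (-0.08 and 0.12) and abscisic acid at 8 h (-0.23 and 0.10), 16 h (0.01 and -0.03) and 20 h (-0.09 and 0.07). The same held for jasmonate at 16 h (-0.15 and 0.19) and 20 h (-0.03 and 0.29), pectin-degrading enzymes at 4 h (-0.02 and 0.48) and ethylene response factors at 8 h (-0.05 and 0.06).

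Of 195 cutin, suberin and wax enzymes 47 rose and 47 fell at 12 h (37 and 56 with the array median), and a lipid transfer protein (contig17484) rose by log2 10.02 ± 0.42 by 20 h (adjusted p = 2.66e-06). Their median and mean differed in sign at 12 h (-0.17 and 0.03) and 20 h (-0.04 and 0.21). Of 243 heat shock proteins 43 rose and 37 fell at 12 h (41 and 48 with the array median), and Hsp20 (contig18467), a small chaperone, fell by 5.37 ± 0.16 (adjusted p = 8.81e-07). Of 267 senescence and protease transcripts 45 rose and 72 fell at 12 h, the ribonuclease contig21191 rising by log2 5.88 ± 0.24; at 4 h the split of 22 and 13 (23 and 18 adjusted over the list alone) was 16 and 21 with the array median. Their median and mean differed in sign at 20 h (-0.11 and 0.07), as did those of photosynthesis at 12 h (-0.03 and 0.01), where 15 rose and 12 fell (15 and 10 adjusted over the list alone), or 9 and 27 with the array median.

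Markers of other tissues and reference genes were followed as well. Of 32 pollen and anther markers 13 rose and 11 fell at 12 h (11 and 12 with the array median), contig26597 being at least 4.27-fold higher. Their medians and means differed in sign at 4 h (0.01 and -0.25) and 8 h (-0.33 and 0.01). Of 21 vascular markers, called as a list at 4 h only, 3 rose and 0 fell by limma at 12 h (7 higher and 1 lower at an unadjusted p under 0.05). At 16 h 6 rose and 0 fell by limma (8 higher and 0 lower at an unadjusted p under 0.05; list adjusted p = 0.0797), and at 20 h 4 rose and 1 fell (median -0.09, mean 0.37). Of 5 markers of dividing cells 1 rose and 1 fell at 12 h, and at 20 h the AT1G62360 probe (SHOOT MERISTEMLESS) stood at log2 2.00 ± 0.32. Of 143 reference genes 14 rose and 22 fell at 12 h, and elongation factor 1-alpha (contig11391) was not called at 4, 12 or 20 h (log2 0.05, -0.12 and -0.47).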

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

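The tests of knotted-like antisense probes and of other groupings of the 12 arrays were set in advance. The difference between 20 and 4 h, the test of the general antisense signal, the count of antisense rises over all contigs, the split of the time points and the enumeration of exchanged arrays were chosen only after the results were seen.

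Some transcripts turned between 4 and 20 h. A group of 44 was higher at 4 h and lower at 20 h than at 0 h, and 42 were lower at 4 h and higher at 20 h, in each case with limma also calling the difference between 20 and 4 h. Of the 42, contig16262 and contig22432 were above background on 0 arrays at 0 h and at 4 h, so their fall at 4 h was not established. The genes named here were chosen after their values were seen. Allene oxide synthase (contig30172), an enzyme of jasmonate synthesis, stood at log2 1.26 ± 0.34 at 4 h and -3.80 ± 0.34 at 20 h (difference -5.06, adjusted p = 6.75e-05, n = 2), and allene oxide cyclase (contig29513) at 1.78 ± 0.31 and -2.17 ± 0.31. The cytochrome P450 contig21900 moved from log2 3.31 ± 0.47 to -4.11 ± 0.47. In the other direction, a pectate lyase (contig9114) moved from log2 -1.11 ± 0.29 to 4.94 ± 0.29 (difference 6.06, adjusted p = 2.28e-05), an expansin (contig6145) from -2.62 ± 0.42 to 2.37 ± 0.42 and the chlorophyll a-b binding protein 13 (contig15853) from -1.40 ± 0.28 to 2.75 ± 0.28. Many more of the 42 were chlorophyll a/b binding contigs with like courses, such as contig5579 (log2 -1.44 and 1.31) and contig6606 (-1.19 and 1.49). Among the 44, lipoxygenase came up more than once, as LOX1.1 (log2 2.13 and -1.65) and contig23841 (2.18 and -1.73). The members of both groups are therefore not all separate genes or families. No explanation of these turns was tested.

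Signal was also present on probes named antisense, of which 13947 were well above background on all 12 arrays. For 5927 tested contigs the antisense probe was the brightest. Which strand of a contig is the coding one could not be checked without sequences or positions. The sense probe of the knotted-like contig17683, dimmer than its antisense probe and so outside the counts above, had a log2 fold change of -4.75 at 12 h against 0 h while the antisense probe rose by 7.19 ± 0.76. The sense probe was below background on both arrays at 12 h, so its fall is only known to be at least 12.3-fold.

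The contrast between the strands of contig17683 was weighed. If the transgene made antisense RNA after flower removal, an antisense probe of a knotted-like contig would rise at 8 h or later without a rise on the sense strand; of the 3 contigs with such a probe above background, 1 did, by log2 7.19 at 12 h. The prediction was written for contigs. Of 4 other knotted-like antisense probes above background, those of TKN4 (log2 -1.21 at 12 h), LeKNOTTED_C1 (-2.01) and LeKNAT1-like (0.17) did not rise. That of Arabidopsis KNAT1 rose by log2 1.60 at 8 h and 2.28 at 16 h, with its sense probe below background throughout. A general rise of antisense signal, as labelling might give, would need a median change of at least 1 over all antisense probes. The median was 0.291 at 12 h (0 for sense probes) and 0.419 at 16 h (0.024), which argues against such a rise as the whole cause. A smaller general lean was present. At 12 h 4572 antisense probes were called higher and 1981 lower, against 6364 and 6311 of the sense probes. The cause of this lean was not tested. Among 18206 antisense probes with a detected sense partner, 1392, contig17683 among them, were called higher without a sense rise. No other of the 1392 rose as far, yet over all antisense probes above background the rise of contig17683 ranked only 8. With so many such rises, natural antisense RNA remains open, and which strand of each contig is the coding one was not checked. Whether contig17683 is the targeted KD gene stays open too, and without an untransformed line an effect of the transgene cannot be separated from the course of abscission.

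The count of 7685 between separated and attached zones was compared with other groupings of the arrays. In a model with 2 groups alone the real grouping called 7045 transcripts, and 1 of 100 groupings drawn from all possible ones, the real one, called as many; the highest of the others drawn was 14, which excludes, at a share under 0.05, only a chance assignment of single arrays. Nearly all such groupings part the replicates of a time, so the low counts of the others do not exclude differences between times that are unrelated to separation. Of all 36 groupings that exchange 1 array of each side, 11 were among those drawn and 5 called more than 0, and exchanging replicate 1 at 8 h with replicate 2 at 12 h called 4743. An earlier draw had held that grouping, and the number was therefore looked up for all 36. Among the 10 ways to divide the 6 times into groups of 3, 1 called as many as the real 7685 and the highest other called 4125; these ways are too few for a share under 0.05.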

How the results depend on the processing

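Sense-strand probes alone, lists without members matched by chance and lists without replicate 1 at 12 h were tried only after the data were seen; the other alternatives were set in advance. Of 7850 values of named genes over 847 gene comparisons, 7423 kept their side of the threshold, 354 lost the call, 67 gained one and 6 reversed. Of 1665 list values over 185 tests 1524 kept their side, 87 lost the call and 54 gained one. Direction was compared only where the reported fit had a call. Values without a call in either fit therefore count as kept whatever their sign.

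Quantile normalization, the array median, the deposited log2 values, no filter on dim probes, probes above background on all arrays, the mean of detected probes and the trended prior left every count of changed transcripts within 1.5 times, as did sense-strand probes alone, with 3264 at 4 h and 7238 between separated and attached zones. Normexp gave 4349 for that last count, in place of 7685, with the other counts within 1.5 times; the cause was not tested. Every probe tested by itself gave 12130, 19228, 21459 and 18504 at 8, 12, 16 and 20 h and 11805 for separated against attached zones, because more units were tested. Adjusted p alone gave 5884, 13439, 20114, 21215 and 19430 from 4 to 20 h, 3110 from 4 to 8 h, 4722 from 8 to 12 h and 22202 for separated against attached zones, since small changes then count. The replicate block gave 167 from 12 to 16 h, and the cause was not tested. Array weights gave 1616 from 8 to 12 h and 10 from 12 to 16 h. They were 0.512 for each array at 12 h and 0.638 at 16 h, against 1.636 at 0 h. The design gives both arrays of a time the same weight, since their residuals are equal and opposite. The weights therefore cannot tell the dim replicate 1 at 12 h from replicate 2. The SD of the difference between replicates was 0.612 at 12 h and 0.535 at 16 h, against 0.376 at 0 h. The reported fit assumes the same spread at every time, so its errors may be too small at 12 and 16 h. With the compared arrays alone, and so fewer degrees of freedom, the counts were 1196 from 4 to 8 h, 252 from 8 to 12 h and, by limma, 0 from 12 to 16 h and 0 from 16 to 20 h, where 3188 and 4999 had an unadjusted p under 0.05. The comparison of separated with attached zones uses all arrays in any case. Slide as a block could not be fitted for the comparisons between slides. Within a slide it left the counts as they were, which the design fixed in advance because each slide holds whole times. It is therefore no test of a slide effect.

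Leaving out 1 array at a time gave 1756 to 2461 at 4 h (3576 with all), 6012 to 6840 at 8 h, 9371 to 14040 at 12 h, 10946 to 13856 at 16 h, 10350 to 11750 at 20 h and 7119 to 8480 for separated against attached zones. It gave 830 to 1478 from 4 to 8 h, 766 to 5116 from 8 to 12 h, 45 to 281 from 12 to 16 h and 123 to 672 from 16 to 20 h. A time left with 1 array was assumed to vary like the others.

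Camera called 67 of 185 list tests, 0 with an estimated correlation (16 at an unadjusted p under 0.05) and limma's fry 102; the counts of calls under the other list alternatives ran from 61 with the mean of detected probes to 71 with quantile normalization, with 64 without replicate 1 at 12 h. With normexp the ethylene receptor contig23823 stood at log2 0.10 at 20 h (-1.87 in the fit reported), on a probe below background at 20 h. With sense probes alone contig17683 stood at log2 -2.53 at 4 h, -4.75 at 12 h and -5.60 at 20 h (below background at both later times, so at least 12.3-fold and at least 12.6-fold lower), and histone H2B (contig19502) at -0.26 at 4 h and -0.49 at 12 h, where their antisense probes had been the brightest and rose. Probes close to background set how small a signal could be followed: 52% to 60.2% of probes were well above it.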

Other observations

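The test of time of day was chosen only after the clock results were seen; the test of the slides was set in advance.

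Steps between slides and steps within a slide were set side by side because slide runs with time. If a slide or scan effect moved probes, the spread of the 7 bright spike-in probes would be at least 1.5 times as large over the 2 steps between slides as over the 3 within. The ratio was 1.22, and 1.08 to 1.62 when 1 probe was left out, so the spike-ins did not settle whether a slide effect may have added to the comparisons between slides. Steps within a slide called 3576, 2718 and 677 transcripts, and steps between slides 1964 and 278. The mean normalized log2 signal of the spike-ins was 5.29 and 5.42 on the arrays at 0 h. It was 6.57 and 5.49 at 12 h and 6.26 and 5.97 at 16 h. Scaling to the spike-ins would thus lower all transcripts at these times against 0 h, and was not tried.

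Clock transcripts were called down against 0 h at 8, 12 and 16 h with the preset correlation, but not with an estimated one (adjusted p = 0.401, 0.406 and 0.506). The time of day at sampling is a candidate explanation. If it were the cause, clock members would return toward the 0 h level by 20 h more than other transcripts did. The test used the 21 of 25 members left without matches of words by chance. The 10 of these called at 16 h changed by a median of log2 -0.73 in absolute fold change from 16 to 20 h, against -0.16 over all 13011 called transcripts, and 7 of the 10 came nearer to 0 h, against 64% of all. That median lay at percentile 0.59 among 10000 random sets matched on the change at 16 h, as time of day would give. A first version without matching gave 0.19. The random sets held transcripts drawn singly, whereas list members may move together, so the percentile may overstate how rare such a median is. The share that came nearer to 0 h, 7 of 10, differed little from the 64% of all. Time since removal runs with time of day in this design, so they were not separated.

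The LOB domain protein contig23050 rose by log2 7.30 ± 0.45 by 20 h and LOB domain protein 25 (contig25353) by 8.20 ± 0.37, while another LOB protein (contig15195) fell by 5.01 ± 0.41 (n = 2). The cytokinin response regulator contig5608 rose by log2 3.24 ± 0.32 at 20 h and a second one, contig20462, stood at -3.89. The 20-oxidase of gibberellin synthesis (contig17199) rose by log2 6.15 ± 0.59 by 20 h. All of these were already called at 4 h, but contig17199 and contig20462 lost that call without replicate 1 or 2 at 0 h (log2 2.46 and 2.76, and -2.23 and -1.95) or replicate 1 at 4 h (log2 1.64 and -1.54). These genes were named by the rule set in advance.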
